A study of Mus musculus with 32 samples.

How the data were processed

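Sympathetic neurons from newborn mice were grown on trans-well membranes for at least 14 days in medium with 10 uM Ara-C, which acts against dividing cells, so that cell bodies stayed on the upper side and axons grew through the pores to the lower side. One set of cultures stayed in medium with nerve growth factor (NGF) throughout (Control). The other set was kept without NGF for 18 h and then given NGF again for 1 h (Restim). RNA was collected separately from the upper side (cell bodies) and the lower side (axons). From each RNA, 10% was saved as input, and the rest was sheared to about 200 bp and precipitated with an antibody to N6-methyladenosine (m6A), which gave the IP library. The 8 groups (NGF state, compartment, input or IP) each held 4 biological replicates, which gave 32 libraries.

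The deposited table holds counts per gene for each library, and the same counts divided by a size factor per library, which the authors call normalised counts (a signal per gene on the scale of counts). The submitters' processing notes name the genome build GRCm38 and the tools FastQC, SAMtools, Trim Galore, DESeq2 and edgeR, without versions or roles. The aligner, the read counter and the annotation are not given in the sources used here, and neither is the treatment of strand or of reads shared between paralogs and pseudogenes, so values of genes with near-identical copies, such as ribosomal protein genes, are uncertain. The table holds 17697 genes, each with at least 10 counts in at least 3 libraries. Symbols of 15285 genes (86.4%) matched the mouse RefSeq annotation of GRCm38, which gave the gene positions. No reference genome and no reads were used.

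The normalised columns equal the counts over a size factor per library (within 1% of the count) for every gene except Trp53inp2, for which 27 of 32 cells hold the value of the library 5 columns to the right. Only the counts were analysed. The table holds values per gene, so m6A was measured as IP over input of a whole gene, and no m6A site or peak can be placed within a transcript. The input was saved before shearing, so the IP was sheared and the input, as described, was not.

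Total counts lay between 1388181 and 58562450 per library. CPM values (counts scaled to a common library size) were computed from the counts with TMM scaling factors in edgeR 4.0.16 (limma 3.58.1, R 4.3.3) and are given as mean ± SD over 4 libraries. A gene at 0 in all 4 libraries of a group is limited to 3 counts over the group, which is 0.081 CPM in Control axonal inputs and 0.1 CPM in Restim axonal inputs. Such floors cover counting error at most, since PCR reads without molecular identifiers are not independent molecules. The SDs and SEs given below also hold the spread between libraries. No fold change is given for genes at 0 in all 4 libraries of a group.

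Groups were compared with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest, TMM scaling, filterByExpr on the libraries of each fit), and genes with a Benjamini-Hochberg adjusted p under 0.05 passed. All adjusted p values of single genes come from this test, and n is 4 per group. Log2 fold changes are edgeR's. Their SE was taken as the absolute log2 fold change over the square root of the test's F statistic. In 3 fits the p values matched a normal distribution of log2 over SE. These were IP over input in Restim axons, and transcripts and IP over input between NGF states in axons. There the spread was pooled over all genes, so p does not measure the spread of 1 gene between samples. Transcript levels were compared in the inputs, between compartments within each NGF state, between NGF states within each compartment, and as the interaction of both. IP over input was tested in each of the 4 conditions, and differences of IP over input were tested between compartments, between NGF states and as the interaction. IP and input of a condition with the same number come from 1 RNA, so fits that hold IP libraries had the RNA sample as a block. Over genes, the deviations of an IP from its group mean correlated with those of its own input at r between 0.16 and 0.62 in cell bodies, where each of the 8 IPs was closest to its own input, and between -0.08 and 0.20 in axons, where 2 of 4 IPs in Control and 4 of 4 in Restim were closest to their own input. Replicate numbers of different conditions have no stated link, so fits on inputs alone had no block.

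Gene groups came from 24 lists of cell type markers, NGF response, stress, axon, synapse, RNA and organelle genes. Each list with at least 4 measured members was tested with limma's camera (preset correlation between genes of 0.01), with Benjamini-Hochberg adjustment over the lists of a comparison, and again with a correlation estimated from the data. This test sets a list against the other genes of the fit and not against 0. Lists called higher or lower below are so relative to those genes. For transcripts between compartments, the median log2 of all genes was -1.28 in Control and -1.98 in Restim. Of 311 list tests, 57 passed with the preset correlation and 0 with the estimated correlation, so the adjusted p with the estimated correlation stands beside each list that passed. Genes named in the text were taken by a rule: in each comparison the 6 genes with the largest rise and the 6 with the largest fall among those that passed, with a mean log2 CPM of at least 3, a symbol that is not a predicted model, and no overlap between the groups (or the pairs all on 1 side), up to 4 members of each list with the smallest p, and Ntrk1, Ngfr, Th, Trp53inp2, Impa1, Actb, Fos, Egr1, Arc, Mettl3, Fto and Malat1. Not every gene the rule takes is printed. Groups, tests, lists, this rule and the alternatives were fixed before the data were examined, except where the text says otherwise.

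Alternatives were DESeq2 size factors (RLE) or total counts in place of TMM, DESeq2 1.42.0 in place of edgeR, no filter or a stricter one (5 CPM in at least 4 libraries), the block left out or a replicate block added, all libraries in 1 fit, IP libraries alone for differences of IP over input, and each replicate left out in turn. Alternatives chosen after the data were seen were fits without RNA samples whose input detected fewer than 3000 genes, without 50 genes of structural RNA, on genes read in every axonal input, and without the RNA samples numbered 4 of both NGF states in cell bodies. The tests were also run on simulated data with known changes of 2-fold to 64-fold. Of changes of 4-fold, 70% were recovered for transcript levels between NGF states in cell bodies, 94% for IP over input in Restim cell bodies, and 0% in comparisons that used axonal inputs. At 64-fold, between 0% and 42% were recovered in the comparisons that used axonal inputs, by comparison and by the genes changed. Between compartments, the simulated fits called at most 26 genes, and 0 with changes put into genes drawn from all genes. The real fits called 2712 and 2532 genes for transcripts and 1858 and 1430 for IP over input. The simulated data thus differ from the real data there, so these percentages do not measure the power of those real fits. For IP over input between NGF states in axons, 5 of 6 simulated calls were genes without a change.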

Results

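The series measured transcript levels and N6-methyladenosine (m6A) precipitation of mouse sympathetic neurons on trans-well membranes, in cell bodies and axons, under continuous NGF (Control) or after 18 h without NGF and 1 h with NGF again (Restim). Each of the 8 groups held 4 libraries, and counts were read per gene. Cell body inputs held 10164105 to 33160449 counts and 10784 to 16316 genes with at least 1 count. Axonal inputs held 1388181 to 24910149 counts and fewer genes, 4804 ± 2050 in Control (SD, n = 4) and 3902 ± 4512 in Restim. In Restim, 1 axonal input held 10592 genes and the others 1003, 1397 and 2618. Cell body IP libraries held 9069552 to 58562450 counts, with 16398 ± 745 genes in Control and 16195 ± 928 in Restim. Axonal IP libraries held 1906430 to 18902733 counts, with 8342 ± 3808 and 8892 ± 3801 genes. Between replicates, log CPM correlated across 5394 genes, which are not independent replicates, at r of 0.74 to 0.96 in cell body inputs, 0.88 to 0.97 in cell body IPs, 0.21 to 0.34 in axonal inputs and 0.28 to 0.72 in axonal IPs.

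**Figure D1:**
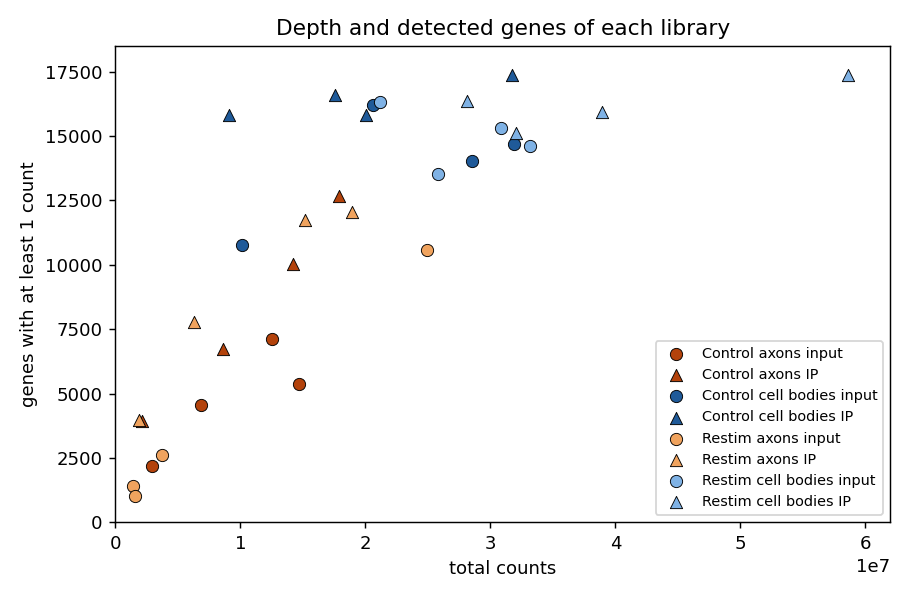
Total counts (x axis) and genes with at least 1 count (y axis) of each of the 32 libraries, with colour for NGF state and compartment, circles for inputs and triangles for IPs. Axonal inputs lie between 1003 and 10592 genes and cell body inputs between 10784 and 16316.

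Which transcripts reached axons under continuous NGF was addressed by axonal against cell body inputs of Control cultures. Transcripts of the sympathetic neuron were lower in axons. Ngfr, the low-affinity neurotrophin receptor, stood at 3601 ± 632 CPM in cell bodies and 457 ± 283 CPM in axons (SD, n = 4 each), 8.5-fold lower (log2 -3.09 ± 0.47 SE, adjusted p = 0.00226). Th, the rate-limiting enzyme of catecholamine synthesis, was 10.5-fold lower (adjusted p = 0.00567). Map1b and Tuba1a, a microtubule-associated protein and a tubulin, were 9.35-fold and 6.8-fold lower (adjusted p = 0.00226 for each). The neurofilament gene Nefl was 5.08-fold lower (adjusted p = 0.00956) and the adhesion molecule Ncam1 6.47-fold (adjusted p = 0.00353). Each of these genes had no overlap between the 4 axonal and 4 cell body libraries. Syn2, a synaptic vesicle protein, Slc6a2, the noradrenaline transporter, Ache, acetylcholinesterase, and the secretory granule gene Scg2 were at 758 ± 157, 699 ± 390, 668 ± 150 and 598 ± 272 CPM in cell bodies and at 0 in all 4 axonal inputs. Of 22 sympathetic neuron genes 11 fell and 0 rose (14 fell when adjusted over the list alone). The list was lower (camera adjusted p = 1.57e-04, adjusted p = 0.232 with an estimated correlation). Summed over that list, CPM fell from 16660 ± 3010 to 1016 ± 186.6. Of 24 synaptic vesicle genes 5 fell, and the list was lower (adjusted p = 0.00792, adjusted p = 0.334 with an estimated correlation). Of 28 genes of axonal cytoskeleton and growth 11 fell, but the list did not pass (adjusted p = 0.061).

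Matrix genes went the other way in Control. Postn, a matrix protein, rose 8.5-fold from 56.1 ± 4.71 to 517 ± 261 CPM (adjusted p = 0.00331), and Col5a1, a collagen chain, and Sparc, a matrix glycoprotein, rose 6.28-fold and 4.74-fold (adjusted p = 0.0108 and 0.0112). Of 18 fibroblast and mural cell genes 17 were higher in axons, 5 rose and 1 fell (7 and 1 when adjusted over the list alone). The list was higher (camera adjusted p = 5.22e-14, adjusted p = 0.232 with an estimated correlation). Its summed CPM was 3841 ± 2534 in cell bodies and 19640 ± 12590 in axons. Of 13 satellite glia and Schwann cell genes 3 rose and 2 fell, and the list was higher (adjusted p = 5.09e-06, adjusted p = 0.232 with an estimated correlation). Without Ngfr, that list summed to 827.8 ± 106.4 CPM in cell bodies and 1196 ± 517.9 in axons. Mlph, an adaptor in organelle transport, Rhbdf1, an inactive rhomboid protein, and Gas7 rose 30-fold, 28.4-fold and 16-fold (adjusted p = 0.00239, 0.00226 and 0.0121). The mitochondrial ribosomal RNA mt-Rnr1 rose 39.9-fold (adjusted p = 0.0104). Of 79 cytosolic ribosomal protein genes 67 were higher and 1 rose (0 when adjusted over the list alone). Of 12 mitochondrially encoded protein genes 11 were higher and 2 rose (6 when adjusted over the list alone). Both were higher as lists (camera adjusted p = 1.65e-17 and 1.59e-10, each with adjusted p = 0.232 with an estimated correlation). Of these genes mt-Nd2 and mt-Cytb, of respiratory complexes, passed at 4.44-fold and 3.69-fold (adjusted p = 0.0408 and 0.0459). mt-Co1, at 5708 ± 3786 CPM in cell bodies and 19837 ± 10560 in axons, did not pass (adjusted p = 0.051). The calls of mt-Nd2 and mt-Cytb ended without cell body libraries 1, 2 or 3 or axonal libraries 2 or 3 (adjusted p up to 0.142 and 0.164). That of mt-Nd2 also ended without axonal library 1.

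Trp53inp2, a gene of autophagy and nuclear receptor signalling (chromosome 2, 155381811 to 155389847), stood at 289 ± 80.9 CPM in Control cell bodies and 1438 ± 1047 CPM in Control axons, 4.75-fold higher (log2 2.25 ± 0.65 SE, adjusted p = 0.0347), with overlap between the libraries. Its call ended when cell body library 1, 2, 3 or 4 (adjusted p = 0.0991, 0.0756, 0.0986 and 0.124) or axonal library 1 or 2 (adjusted p = 0.0666 and 0.0773) was left out, and with no filter (0.0573). Actb, often used as a reference, was at 1899 ± 85.1 and 1549 ± 450 CPM (adjusted p = 0.495), and Malat1, a nuclear RNA, at 7578 ± 2065 and 14499 ± 8762 CPM (adjusted p = 0.27). Malat1 passed with total counts as the scaling (adjusted p = 0.00847).

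Over all 10945 genes tested in Control, 82 were higher and 2630 lower in axons. Of the 2630 lower genes, 2420 were at 0 in all 4 axonal inputs, and every gene tested that was at 0 in all 4 was called. Among 1105 genes read in all 4 axonal inputs, 82 were higher and 59 lower. A fit on these genes alone, chosen after the data were seen, gave 156 higher and 83 lower. Without axonal library 1, 4202 genes were called, with the stricter filter 1744, and with a replicate block 253. With all libraries in 1 fit 4345 were called, and Ngfr, Th, Tuba1a and Nefl did not pass (adjusted p = 0.0748, 0.155, 0.0804 and 0.305), nor did Postn, Mlph, Rhbdf1 and Gas7 (0.261, 0.135, 0.084 and 0.236). Another 3 lists passed upward without a gene that rose. The lists of immediate early genes, ERK feedback genes and regulators of transcription had positive tests (adjusted p = 0.0296, 0.0383 and 0.00792, each with adjusted p = 0.514 with an estimated correlation). Among their 25, 24 and 30 genes 0 rose and 2, 2 and 0 fell, and the medians of the first and the last were negative.

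In Restim cultures the same comparison again had neuronal transcripts lower in axons. Map1a, a microtubule-associated protein, fell 8.74-fold, from 2514 ± 245 to 288 ± 122 CPM (log2 -3.13 ± 0.57 SE, adjusted p = 0.00391). Bsn, a presynaptic scaffold, Sptbn2, a spectrin of the membrane skeleton, Sv2a, a synaptic vesicle protein, and Chrna3, a nicotinic receptor subunit, were at 768 ± 40.5, 489 ± 86.2, 354 ± 43.3 and 299 ± 108 CPM in cell bodies and at 0 in all 4 axonal inputs. Ngfr was at 4070 ± 706 and 250 ± 295 CPM and Th at 2882 ± 259 and 19.3 ± 38.7 CPM, and neither passed (adjusted p = 0.239 and 0.149). Of 22 sympathetic neuron genes 8 fell and 0 rose (16 fell when adjusted over the list alone). The list was lower (camera adjusted p = 3.75e-04, adjusted p = 0.545 with an estimated correlation), with summed CPM of 19600 ± 2687 in cell bodies and 660.2 ± 223.3 in axons. Mir6236, among the 50 genes of structural RNA, was 44-fold higher in axons (1409 ± 857 CPM, adjusted p = 0.00461). The intermediate filament gene Nes was 7.45-fold higher (adjusted p = 0.0482), a call that ended without cell body libraries 1, 2 or 3 or axonal library 3 (adjusted p up to 0.16).

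Of 17 fibroblast and mural cell genes 14 were higher in Restim axons and 0 passed. The list was higher (camera adjusted p = 2.91e-13, adjusted p = 0.545 with an estimated correlation). Its summed CPM was 3466 ± 1390 in cell bodies and 13640 ± 9463 in axons. Col1a2 and Col5a1, collagen chains, were at 4.69-fold and 5.53-fold (adjusted p = 0.0524 and 0.0687). They passed with RLE scaling (0.0159 and 0.0234) and with total counts (0.00611 and 0.00856). Trp53inp2 was at 438 ± 78.8 CPM in cell bodies and 615 ± 225 CPM in axons (log2 0.48 ± 0.69 SE, adjusted p = 0.768). Over 12466 genes tested, 10 were higher and 2522 lower, 2351 of them at 0 in all 4 axonal inputs. Among 248 genes read in all 4 axonal inputs, 10 were higher and 3 lower. Without axonal library 4, which held 10592 genes, 9064 genes were called, with the stricter filter 1087, and with a replicate block 3. Lists of ribosomal protein, immediate early, translation factor, transcription regulator and NGF deprivation genes had positive tests and negative medians (adjusted p = 3.72e-04, 0.0158, 0.0266, 0.0434 and 0.0494, each with adjusted p = 0.839 with an estimated correlation). In these lists 9 of 80, 14 of 31, 6 of 28, 7 of 30 and 8 of 24 genes were higher in axons, and 0 rose. The median log2 of all genes was -1.98, so a positive test here means less lowered than the other genes.

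**Figure D2:**
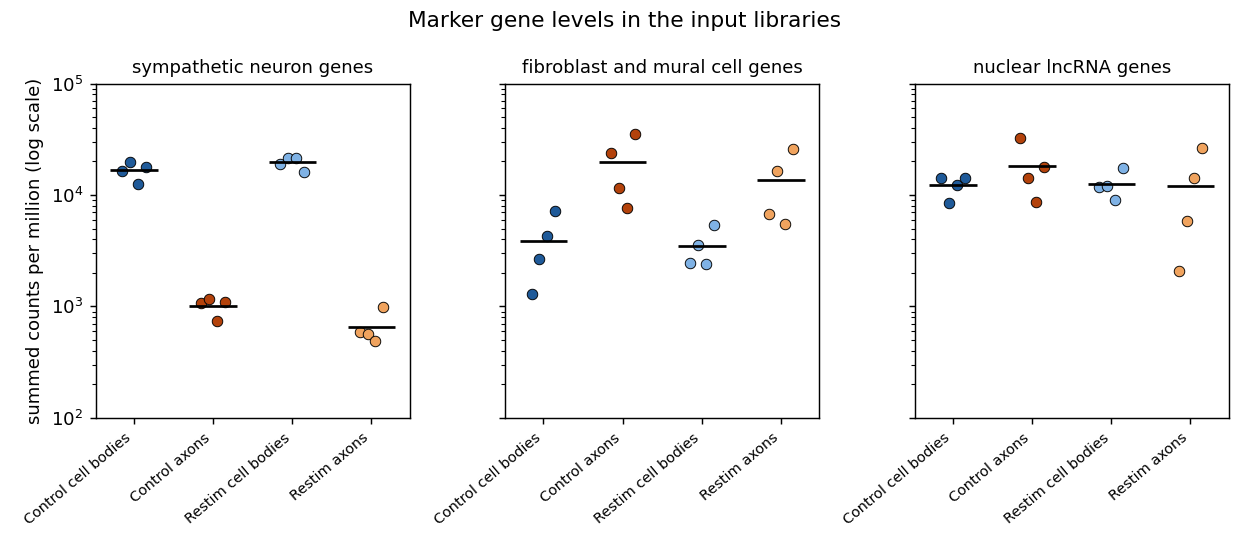
Summed CPM (log axis) of the sympathetic neuron, fibroblast and mural cell, and nuclear lncRNA lists in each input library, with a bar for the mean of the 4 libraries of a group. Mean sympathetic neuron CPM was 16660 in Control cell bodies and 1016 in Control axons, and mean fibroblast and mural cell CPM 3841 and 19640.

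Transcript levels after NGF withdrawal and return were compared with continuous NGF in cell body inputs. Plxna4, a receptor for axon-guiding semaphorins, was at 647 ± 92.9 CPM in Control and 1297 ± 96.5 CPM in Restim, the smallest p of this comparison (log2 0.94 ± 0.14 SE, adjusted p = 0.466). It passed when adjusted over the axon guidance list alone. Egr1, an immediate early transcription factor, was at 105 ± 39.7 and 181 ± 36.9 CPM (log2 0.75 ± 0.24 SE), Fos at 18.6 ± 5.21 and 24.8 ± 8.94 CPM and Arc at 7.11 ± 6.65 and 4.88 ± 2.66 CPM, each with adjusted p = 1. The immediate early list had 20 of 31 genes higher (adjusted p = 0.105). Chac1, a stress-induced enzyme of glutathione breakdown, was at 39.5 ± 12.2 and 75.8 ± 15.6 CPM and Pmaip1, a pro-apoptotic gene, at 50.9 ± 11.7 and 22.4 ± 14.5 CPM, both with adjusted p = 1. The neuronal genes Th, Ngfr and Ntrk1, the NGF receptor, had log2 changes of 0.24, 0.12 and -0.19, and the m6A genes Fto, an eraser, and Mettl3, the writer's catalytic subunit, 0.14 and -0.05, each with adjusted p = 1.

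Some lists moved as a whole, with 0 members past the threshold in any. Mitochondrially encoded protein genes (11 of 12 higher, camera adjusted p = 1.89e-07) and cytosolic ribosomal protein genes (71 of 80, 5.06e-07) were higher in Restim cell bodies. So were nuclear genes of oxidative phosphorylation (68 of 79, 6.68e-07) and known axonal mRNAs (22 of 25, 0.00586). Cholesterol synthesis genes (3 of 22 higher, 0.00132), with Dhcr7 at 132 ± 14.8 and 86.9 ± 18 CPM, were lower. Lower too were the lists of macrophage (2 of 12 higher, 0.00242), fibroblast and mural cell (5 of 19, 0.0185) and satellite glia and Schwann cell genes (3 of 13, 0.0392). Apoe, a lipid carrier, was at 347 ± 192 and 139 ± 96.4 CPM and Sox10, a glial transcription factor, at 23.9 ± 11.5 and 11 ± 4.87 CPM. None of these 8 lists passed with an estimated correlation (adjusted p = 0.765 for each). edgeR called 0 of 14283 genes, with 669 at an unadjusted p under 0.05, and DESeq2 called 29. In simulated data of this comparison, 22% of changes of 2-fold and 70% of changes of 4-fold were recovered.

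In axonal inputs the same NGF comparison called 1 of 3681 genes. Gm29216, a predicted gene with no matched position, was at 1131 ± 1177 CPM in Control axons and 0.526 ± 0.607 CPM in Restim axons (adjusted p = 0.0165). It is named after its values were seen, as the 1 gene that passed. Its call ended without Control axonal library 2, 3 or 4, each of which left 0 genes by edgeR, and without Restim axonal library 1, 2 or 4 (adjusted p = 1, 1, 0.0634, 0.0702, 0.336 and 0.117). It also ended with no filter (0.202), a replicate block (0.447) and all libraries in 1 fit (0.052). The full fit had 15 genes at an unadjusted p under 0.05, and DESeq2 called 1. Actb was at 1549 ± 450 and 1364 ± 1111 CPM and Trp53inp2 at 1438 ± 1047 and 615 ± 225 CPM, both with adjusted p = 1. Satellite glia and Schwann cell genes (1 of 9 higher in Restim) and ribosomal protein genes (5 of 72) were lower as lists (adjusted p = 0.00407 for each, adjusted p = 0.994 with an estimated correlation). Libraries held 2181 to 7111 genes with counts in Control and 1003, 1397, 2618 and 10592 in Restim. Of simulated changes of up to 64-fold in this comparison, 0% were recovered.

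Whether the difference between axons and cell bodies depended on NGF state was tested as an interaction on inputs. mt-Co1, a subunit of cytochrome oxidase, was at 5708 ± 3786 CPM in Control cell bodies and 19837 ± 10560 in Control axons, against 10908 ± 2788 and 7486 ± 5184 in Restim (log2 -2.39 ± 0.76 SE, adjusted p = 0.119). Of 12 mitochondrially encoded protein genes 0 were positive, 0 passed over all genes and 5 fell when adjusted over the list alone. That list was lower (camera adjusted p = 1.82e-08, adjusted p = 0.81 with an estimated correlation). The 80 ribosomal protein genes, 6 of them positive, were lower as a list (camera adjusted p = 4.74e-11, adjusted p = 0.81 with an estimated correlation). Rps2 did not pass (adjusted p = 0.322). Trp53inp2 had log2 -1.88 ± 1.06 (adjusted p = 0.398). edgeR called 0 of 14127 genes, with 3012 at an unadjusted p under 0.05, and DESeq2 called 1823. Without Restim axonal library 4, 1453 genes were called, and without Restim axonal library 3, 1 gene.

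Which transcripts the m6A antibody took from cell bodies was measured as IP over input. The nuclear-retained Malat1 rose from 7416 ± 2927 to 13484 ± 4977 CPM in Restim, 1.78-fold (log2 0.83 ± 0.05 SE, adjusted p = 0.001), and was at 0.73 ± 0.19 in Control (adjusted p = 0.215). Ncl, nucleolin of the nucleolus (chromosome 1, 86344719 to 86359455), rose 3.8-fold in Control (adjusted p = 0.0233) and 5.23-fold in Restim (adjusted p = 0.00445). Nefm, a neurofilament gene, rose 2.33-fold and 1.95-fold (adjusted p = 0.0277 and 0.0144). The translation factor Eif3a rose 2.05-fold in each (adjusted p = 0.0321 and 0.00987). Hnrnpa2b1, an RNA-binding protein, and Ythdc1, a nuclear m6A reader, rose 2.67-fold and 2.43-fold in Restim (adjusted p = 0.00567 and 0.0257). In Control they stood at 2.2-fold and 2.42-fold (adjusted p = 0.0936 and 0.108). The mitochondrial message mt-Nd6 rose 7.55-fold in Control (adjusted p = 6.54e-04) and 6.46-fold in Restim (adjusted p = 0.021). Every change in this paragraph had all 4 pairs of IP and input on 1 side.

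Other genes were lower in the IP than in the input. Rmrp, the RNA of RNase MRP, fell 4.28-fold in Control (adjusted p = 0.0355) and 5.96-fold in Restim (adjusted p = 5.02e-04). Snora73a, a small nucleolar RNA, fell 19.7-fold and 13-fold (adjusted p = 0.0466 and 0.0157). Also lower in Restim were Th at 1.77-fold, Phox2a, a noradrenergic transcription factor, at 2.12-fold, Ngfr at 1.49-fold and Ntrk1 at 1.52-fold (adjusted p = 0.00614, 0.00661, 0.0099 and 0.0113). So were Col1a1, a collagen, at 2.03-fold and the ribosomal protein gene Rplp1 at 2.3-fold (adjusted p = 0.00497 and 0.00987). In Control, Th, Ngfr, Ntrk1, Col1a1 and Rplp1 had log2 values of -0.64, -0.40, -0.51, -0.98 and -0.86 and did not pass (adjusted p = 0.12, 0.246, 0.161, 0.0643 and 0.0809). Actb was at log2 -0.25 and -0.17 and Trp53inp2 at 0.17 and -0.09 in Control and Restim, and neither passed (adjusted p = 0.392, 0.28, 0.623 and 0.585).

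By list, mitochondrially encoded protein genes had 4 of 12 up in Control (10 when adjusted over the list alone) and 10 of 13 in Restim, with 0 down. Their list was higher in both (camera adjusted p = 4.7e-31 and 1.42e-10, adjusted p = 0.251 and 0.242 with an estimated correlation). RNA transport and axonal RNA-binding genes had 0 of 31 past the threshold in Control (5 up when adjusted over the list alone) and 6 up in Restim, among them Hnrnpa2b1, Pura and Fxr1. This list was higher in both (adjusted p = 8.84e-04 and 2.19e-04, adjusted p = 0.251 and 0.272 with an estimated correlation). The m6A writers, erasers and readers had 0 of 27 in Control (5 up when adjusted over the list alone) and 5 up and 1 down in Restim, with Cbll1, a partner of the writer complex, at 2.93-fold. Their list too was higher in both (adjusted p = 0.0128 and 0.015, adjusted p = 0.648 and 0.242 with an estimated correlation). Ribosomal protein genes had 0 of 80 past the threshold in Control (2 up and 7 down when adjusted over the list alone) and 1 up and 19 down in Restim. As a list they were lower in both (adjusted p = 8.84e-04 and 1.17e-06, adjusted p = 0.648 and 0.242 with an estimated correlation). In Control the fibroblast and mural cell list was lower, with 0 of 19 past the threshold (adjusted p = 0.0106, adjusted p = 0.648 with an estimated correlation).

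A further 4 lists passed in Restim and not in Control, and the test of the difference between the NGF states passed for 0 lists. Translation factors had 9 up and 1 down of 28, with the poly(A)-binding gene Pabpc1 at 1.93-fold and Eif5 at 1.77-fold (adjusted p = 2.55e-04, adjusted p = 0.242 with an estimated correlation). Sympathetic neuron genes had 1 up and 5 down of 22 (adjusted p = 0.0059, adjusted p = 0.242 with an estimated correlation), a list call that ended with total counts as the scaling (adjusted p = 0.194). Integrated stress response genes had 5 down of 24, with Atf4, its main transcription factor, at log2 -0.53 ± 0.09. Immediate early genes had 3 down of 31. Both lists were lower (adjusted p = 0.00622 for each, adjusted p = 0.242 and 0.243 with an estimated correlation). Total counts moved the median log2 of all genes by 0.20 in both NGF states and RLE by -0.02 and 0.01. With total counts Atf4 no longer passed.

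In all, 26 genes were higher and 5 lower in the IP of Control cell bodies (of 14636), and 685 higher and 624 lower in Restim cell bodies (of 15146), 157 and 131 of them by at least 2-fold. All 26 and all 5 of the Control genes were called in the same direction in Restim, against 1.2 and 0.2 for independent lists. DESeq2 called 785 and 2722 genes in Control and Restim, all libraries in 1 fit 0 and 0, and edgeR without the block 32 and 262. With all libraries in 1 fit the call of every gene named here ended (adjusted p = 1 for each). Without the block Malat1 and Rmrp did not pass in Restim (adjusted p = 0.19 and 0.0687). The counts changed when 1 RNA sample was left out: without Control sample 1, 2, 3 or 4 they were 2, 1, 58 and 1, and without Restim sample 1, 2, 3 or 4 they were 468, 10, 718 and 39. Of the genes named here, mt-Nd6 in Control, and Malat1 and Rmrp in Restim, passed in each fit with 1 sample left out. The other Control calls ended without sample 1, 2 or 4 (adjusted p up to 0.409). In Restim the other calls ended without sample 2, and all of these but Ncl, Hnrnpa2b1, Th, Phox2a, Col1a1 and Rplp1 also without sample 4, with those of mt-Nd6 and Atf4 ending without sample 1 as well (adjusted p up to 0.129). Over these fits the log2 of Ncl stayed at 1.79 to 2.05 in Control and 2.25 to 2.68 in Restim, and that of Th in Restim at -0.86 to -0.75.

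**Figure D3:**
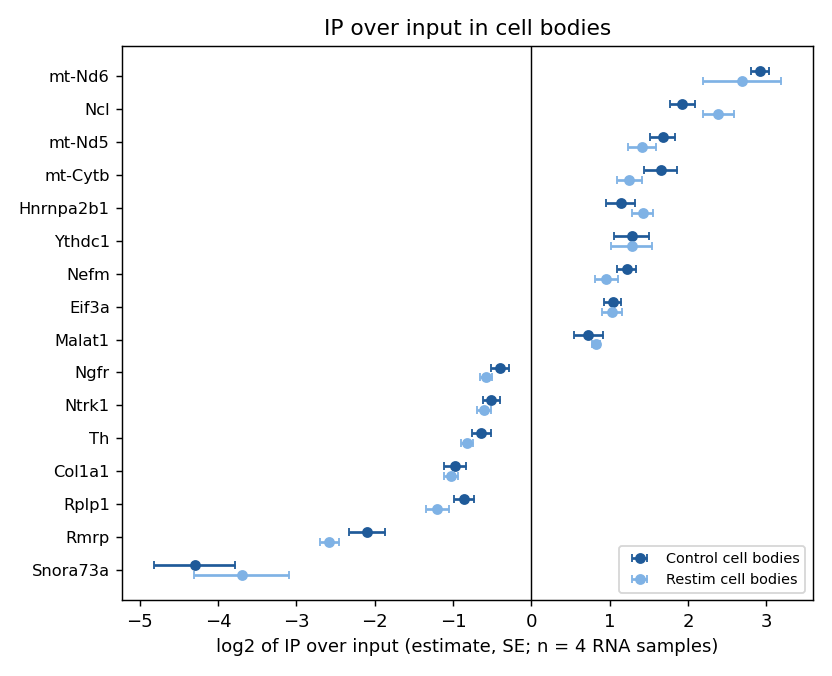
Estimated log2 of IP over input with its SE (x axis) of 16 genes in Control and Restim cell bodies, from 4 RNA samples each. mt-Nd6 lies at 2.92 and 2.69, Malat1 at 0.73 and 0.83, and Rmrp at -2.10 and -2.58.

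In axons, IP over input was read with the same test. In Control, mitochondrial messages led again, with mt-Nd6 rising from 134 ± 88.9 to 3370 ± 1770 CPM, 27.1-fold (adjusted p = 0.00211), mt-Nd5 5.46-fold, mt-Nd2 4.35-fold and mt-Cytb 4.14-fold (adjusted p = 0.00179 for each). Malat1 rose 2.64-fold (log2 1.40 ± 0.11 SE, adjusted p = 0.00179). Akap12, an anchor of protein kinase A, rose 2.14-fold (adjusted p = 0.0493), and Rn7s1, an RNA of the signal recognition particle, fell 1.72-fold (adjusted p = 0.0486). Of 12 mitochondrially encoded protein genes 7 rose (camera adjusted p = 1.02e-04, adjusted p = 0.892 with an estimated correlation). In total 9 genes rose and 1 fell of 6661 (212 had an unadjusted p under 0.05), and DESeq2 called 1054, all libraries in 1 fit 2258, edgeR without the block 1 (mt-Nd6), and a fit on genes read in every axonal input, chosen after the data were seen, 6. Of the genes named here, mt-Nd6 alone passed with DESeq2. Without RNA sample 2, 0 genes were called. Without sample 3, 8 were, and Rn7s1, mt-Co1 and Akap12 lost their calls. Without sample 1, 21 were.

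In Restim axons mt-Co1 rose 3.07-fold, from 7486 ± 5184 to 22084 ± 10170 CPM (adjusted p = 0.0351). Yam1 and Rn7s1, both among the 50 genes of structural RNA, fell 3.24-fold and 3.3-fold (adjusted p = 1.8e-26 and 2.2e-07). The 4 pairs leave 3 residual degrees of freedom. P values this small rest on a spread pooled over all genes and do not measure that of 1 gene between RNA samples. Yam1 has no matched position and was at 107900 ± 45190 CPM in the inputs. Trp53inp2 rose in each of the 4 pairs, from 615 ± 225 to 3240 ± 645 CPM (log2 2.41 ± 1.06 SE), and did not pass (adjusted p = 0.601). Malat1 was at log2 1.48 ± 0.37 (adjusted p = 0.103). Of 7151 genes 1 rose and 2 fell, with 118 at an unadjusted p under 0.05, and DESeq2 called 1395. Without RNA sample 1, 2, 3 or 4 the number was 2, 0, 3 and 4. The mt-Co1 call ended without sample 1, 2 or 3 (adjusted p = 0.173, 0.97 and 0.994) and with RLE scaling (adjusted p = 0.646). That of Rn7s1 ended without sample 1, 2 or 4 (adjusted p = 0.173, 0.97 and 0.606), and that of Yam1 without sample 2 (adjusted p = 0.0782). The calls of mt-Co1, Yam1 and Rn7s1 also ended with DESeq2 (adjusted p = 0.695, 0.243 and 0.252), with no filter (0.857 for each) and on genes read in every axonal input (0.568, 0.256 and 0.482), and those of mt-Co1 and Rn7s1 without the block (1 for each).

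The central question of the series, whether m6A on a transcript differs between axons and cell bodies, was tested as the difference of IP over input. In Control, mt-Nd6 had a ratio 3.53-fold higher in axons (log2 1.82 ± 0.42 SE, adjusted p = 0.0269). Its call ended with total counts (0.0799), DESeq2 (0.363), no block (0.163), all libraries in 1 fit (0.776), on genes read in every axonal input (0.445) and without cell body sample 1, 2 or 4 (adjusted p up to 0.0933). Stau2, an RNA-transport protein (chromosome 1, 16228803 to 16520332), was at 45.1 ± 12.8 CPM in cell body input and 55.2 ± 14.1 in cell body IP, at 0 in all 4 axonal inputs and at 109 ± 91.6 CPM in axonal IP. Golga7, which acts in protein palmitoylation, was at 40.2 ± 8.34 and 52.5 ± 2.44 CPM in cell bodies, at 0 in all 4 axonal inputs and at 98.3 ± 41 CPM in axonal IP. Syn3, a synapsin, was at 77.9 ± 24.1 and 64.8 ± 14.3 CPM in cell bodies, 0 in all 4 axonal inputs and 55.6 ± 46.1 CPM in axonal IP. Trp53inp2, Ngfr and Actb had log2 differences of 0.18, 0.51 and -0.03 (adjusted p = 0.945, 0.427 and 1).

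Of 14503 genes, 1805 had a higher and 53 a lower ratio in Control axons, and 0 of the lists passed. Of the 1805, 1716 were at 0 in all 4 axonal inputs, so that their axonal ratio had no measured input, and in 393 (21.8%) the mean IP CPM was higher in axons than in cell bodies. Among 1111 genes read in all 4 axonal inputs, 3 had a higher and 1 a lower ratio. The adjusted p of mt-Nd6 (0.0269, unadjusted 0.0025 in the edgeR test) rests in part on the small p values of the genes at 0. Without Control cell body sample 1, 2 or 4, edgeR called 0 genes, with 2494, 2631 and 2578 at an unadjusted p under 0.05, and without axonal sample 1 it called 3190. DESeq2 on all samples called 2076, edgeR without the block 1229, and a fit on genes read in every axonal input 0. IP libraries compared alone gave 239 genes higher and 1481 lower in axons.

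In Restim, Trp53inp2 had a ratio 5.63-fold higher in axons than in cell bodies (log2 2.49 ± 0.62 SE, adjusted p = 0.0396). It was at 438 ± 78.8 CPM in cell body input, 428 ± 91.9 in cell body IP, 615 ± 225 in axonal input and 3240 ± 645 in axonal IP. By pair of CPM values, its log2 IP over input was 2.45 ± 0.61 (SD, n = 4) in axons, above 0 in 4 of 4, and -0.04 ± 0.09 in cell bodies, above 0 in 1 of 4. The call ended without cell body sample 1, 2, 3 or 4 (adjusted p = 0.0699, 0.108, 0.141 and 0.099) or axonal sample 1 or 2 (adjusted p = 0.0521 and 0.103). It also ended with RLE scaling (0.113), total counts (0.0955), no filter (0.0921) or no block (0.114). Malat1 and Actb had differences of 0.65 ± 0.50 and 1.03 ± 0.59 (adjusted p = 0.43 and 0.28). Malat1 was at -0.83 without the samples whose input held under 3000 genes, left out after the data were seen, which keeps 1 Restim axonal sample. Mthfd2, a mitochondrial folate enzyme, was at 50.7 ± 14.8 and 67.5 ± 13.3 CPM in cell body input and IP, at 0 in all 4 axonal inputs and at 113 ± 110 CPM in axonal IP. Bsn was at 768 ± 40.5 and 558 ± 39.5 CPM in cell bodies, 0 in all 4 axonal inputs and 26.9 ± 16.4 CPM in axonal IP.

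Of 15112 genes in Restim, 1314 had a higher and 116 a lower ratio in axons, and 0 of the lists passed. Of the 1314, 1217 were at 0 in all 4 axonal inputs, and 353 (26.9%) had a higher mean IP CPM in axons. Among 248 genes read in all 4 axonal inputs, Trp53inp2 alone was called higher and 0 lower. Its unadjusted p was 0.00334 in the edgeR test. The adjusted p of 0.0396 rests in part on the small p values of the genes at 0 in all 4 axonal inputs. In a fit on genes read in all 4 alone, chosen after the data were seen, the adjusted p of Trp53inp2 was 0.228. Without any 1 of cell body samples 1 to 4, edgeR called 0 genes, with 3225 to 3686 at an unadjusted p under 0.05, and without axonal sample 4 it called 7298. DESeq2 on all samples called 3717, edgeR without the block 1, all libraries in 1 fit 595, and a fit on genes read in every axonal input 0. The deposited normalised counts of Trp53inp2 gave another direction. Of its 32 cells, 27 held the value of the library 5 columns to the right, and as deposited the row gave a log2 IP over input in Restim axons of -1.67 ± 1.13, against 1.53 ± 0.86 from the counts over the same size factors, so the counts were used.

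**Figure D4:**
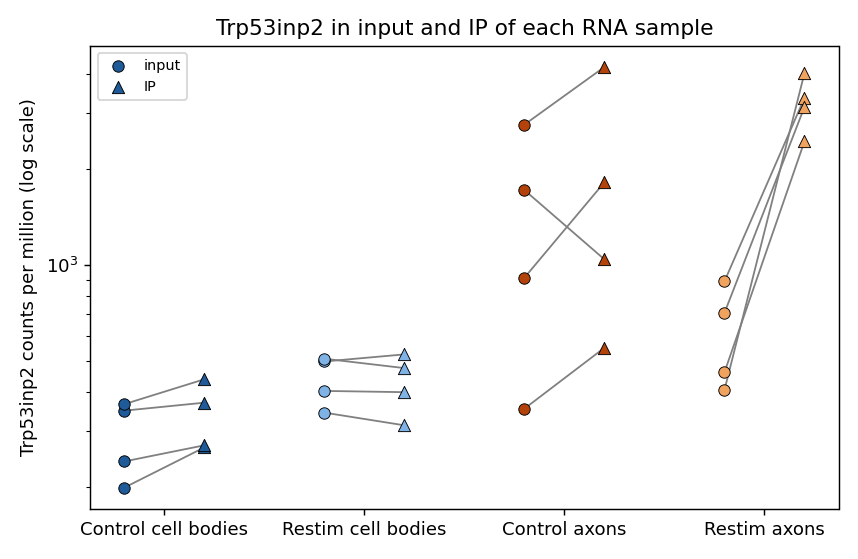
Trp53inp2 CPM (log axis) in input (circles) and IP (triangles) of each RNA sample, with a line joining the libraries of 1 RNA, in 4 conditions. In Restim axons the inputs lie between 405.1 and 889 CPM and the IPs between 2450 and 4014 CPM.

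Whether NGF state changed IP over input within a compartment was tested last. In cell bodies, Trp53inp2 had a log2 difference of -0.22 ± 0.13 SE (Restim minus Control), Egr1 -0.39 ± 0.22, Th -0.15 ± 0.14, Ngfr -0.14 ± 0.14, Ntrk1 -0.06 ± 0.13, Malat1 0.13 ± 0.21, Fto -0.01 ± 0.21 and Mettl3 0.22 ± 0.44, each with adjusted p = 1. edgeR called 0 of 16610 genes, with 430 at an unadjusted p under 0.05 and a smallest adjusted p of 1, DESeq2 called 19, and 0 lists passed. In simulated data, 14% of differences of 2-fold and 66% of differences of 4-fold were recovered.

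In axons, Yam1, among the 50 genes of structural RNA, had a lower ratio in Restim (log2 -1.33 ± 0.26 SE, adjusted p = 0.00534), the 1 gene called of 10647. That call ended without Control sample 1, 2, 3 or 4 and without Restim sample 2, each of which left 0 genes by edgeR. It also ended with DESeq2 (adjusted p = 0.63), with no filter (1), with all libraries in 1 fit (0.164), with IP libraries alone (1) and on genes read in every axonal input (0.663). The full fit had 149 at an unadjusted p under 0.05, and DESeq2 called 422. Trp53inp2 was at 2.10 ± 1.28 (adjusted p = 1) and Malat1 at 0.14 ± 0.46 (adjusted p = 1), or -1.30 without the samples with under 3000 genes in the input, which keeps 1 Restim axonal sample. The lists of ribosomal protein genes (69 of 80 higher), satellite glia and Schwann cell genes (13 of 15), known axonal mRNAs (22 of 25) and transcription regulators (21 of 30) had higher ratios in Restim (camera adjusted p = 3.56e-04, 0.0259, 0.0461 and 0.047, each with adjusted p = 0.87 with an estimated correlation). The lists are set against the other genes, and the median log2 of all genes in this fit was 1.38. Of the list members 0 passed, and Restim axonal inputs held 1003, 1397, 2618 and 10592 genes against 2181 to 7111 in Control. A lower input raises such a ratio, and the ribosomal protein and glia lists were lower in Restim axonal inputs.

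The interaction of compartment and NGF state on IP over input had Trp53inp2 at log2 2.33 ± 0.91 SE (adjusted p = 0.425), Malat1 at 0.02 ± 0.62 (adjusted p = 1) and Actb at 1.08 ± 0.89 (adjusted p = 0.874). Known axonal mRNAs (23 of 25 positive, camera adjusted p = 0.00161), ribosomal protein genes (68 of 80, 8.52e-07) and regulators of transcription (21 of 30, 0.00809) were higher as lists. So were translation factors, m6A genes and satellite glia and Schwann cell genes (23 of 28, 18 of 27 and 14 of 18, 0.0494 each). Each had adjusted p = 0.735 with an estimated correlation, and 0 members passed. The median log2 of all genes in this fit was 0.91. The ratios hold the same inputs as the transcript interaction, so a lower input in Restim axons can raise them. edgeR called 0 of 16288 genes, with 1552 at an unadjusted p under 0.05, and DESeq2 called 1245. Left out in turn, Control cell body sample 3, Control axonal sample 4 and Restim axonal samples 1, 3 and 4 gave 64, 147, 1, 448 and 877 genes.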

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

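All tests in this part except the tests of lists and of single genes were chosen only after the results were seen.

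Several measures of the 8 groups of 4 libraries were tested for a library far from the other 3, and 5 of the 52 tests found one, where chance gives about 1 in 20 (2.6). The tests are not independent, and 2 of the 5 concern Restim axonal input 4. Restim axonal input 4 held 24910149 counts (the others 1388181 to 3767936) and 10592 genes with counts (the others 1003 to 2618). Structural RNA took 34.8% of counts in Restim cell body input 4 (the others 21.1 to 22), 24.8% in Restim axonal IP 4 (the others 13.5 to 15.1) and 19.1% in Control axonal IP 2 (the others 26.4 to 27.3).

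The difference between axons and cell bodies differed with NGF state for 7 lists in the inputs by the interaction test: satellite glia and Schwann cell, known axonal mRNA and transcription regulator genes (camera adjusted p = 0.00936 each), nuclear lncRNA genes (0.0166), ribosomal protein genes (4.74e-11), mitochondrially encoded protein genes (1.82e-08) and nuclear oxidative phosphorylation genes (0.0212) were relatively lower in Restim axons, each with adjusted p = 0.81 with an estimated correlation. For IP over input, satellite glia and Schwann cell, m6A and translation factor genes (0.0494 each), known axonal mRNAs (0.00161), transcription regulators (0.00809) and ribosomal protein genes (8.52e-07) were relatively higher in Restim axons, each with adjusted p = 0.735 with an estimated correlation. These ratios hold the same inputs, and a lower input raises a ratio. In axonal inputs the mean summed CPM of each of these lists was lower in Restim than in Control. In axonal IPs it was lower in Restim for ribosomal protein genes (12660 ± 6456 against 18380 ± 10970), transcription regulators and glia genes. It was higher in Restim for known axonal mRNAs (11610 ± 1970 against 8550 ± 3030), m6A and translation factor genes.

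Most genes lower in axons were at 0 in all 4 axonal inputs, 2420 in Control and 2351 in Restim. If each axonal input missed genes independently, with a chance set by the gene's level in cell bodies alone, 1702 ± 35.3 (SD) would be at 0 in all 4 in Control and 2093 ± 38 in Restim, fewer than observed, which argues against such loss as the whole cause. Among genes over 100 CPM in cell bodies, 119 were at 0 in Control against 13.29 ± 3.63, and 80 in Restim against 34.05 ± 5.77. The chance of a miss was read from these same axonal inputs, so genes absent from axons raise the expected numbers. At 70.4% and 89% of the observed numbers, the expected ones are upper limits for such loss, and its true share was not measured. Such loss, absence from axons and loss that follows other properties of a gene remain open and were not tested apart.

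Fibroblast and mural cell genes were higher in the axonal fraction, 5.11 times in Control by summed CPM, from a list of 19 genes of which 19 were over 1 CPM in Control cell bodies and 0 stand on another list. A candidate explanation, whole non-neuronal cells on the lower side of the membrane, predicts that nuclear RNA is not depleted there (Col5a1 stood at 2118 ± 1186 CPM and Sparc at 1701 ± 730 CPM in Control axons). The mean of Malat1 in axonal inputs was 1.91 times that in cell body inputs in Control, with overlap between the libraries (1.38 times without axonal library 1), which goes with it. In Restim the ratio was 1.38 and turned to 0.758 without axonal library 4 (24040 CPM, the others 1477 to 10610), which decides nothing. All cultures held Ara-C at 10 uM, which acts against dividing cells and would lower the number of such cells. Loss of neuronal RNA alone would raise every other cell type alike. Macrophage genes would then need 1000 CPM in Control axonal inputs, and the highest library held 133.2 CPM, which argues against it. Fibroblast messages within axons remain an open biological explanation that was not tested.

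Trp53inp2 had a higher IP over input in Restim axons than in Restim cell bodies, while its deposited normalised values had 27 misplaced cells. Those 27 cells equal the count and the size factor 5 columns to the right, and 0 equal that count over their own size factor, which argues against an order error in the counts themselves. A shift shared by the genes read in every Restim axonal input had a median of 0.58 with an SD of 1.36 over 248 genes, against 2.49 for Trp53inp2, which ranked 7 by fold and 1 by p. Restim axonal inputs did not lie under cell body inputs (log2 difference 0.48 ± 0.69 SE). This cannot decide on a lower input in Restim axons, since Control axonal inputs stood above cell bodies. From Control to Restim axons, the mean log2 CPM of Trp53inp2 moved by -0.93 in the inputs and by 1.14 in the IPs. A lower input therefore stays open as a part of the cause. The shared shift cannot be told apart from a higher m6A level, since Trp53inp2 lies within 2 SD of those genes, and a dependence on NGF state stays open (interaction adjusted p = 0.425).

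Other splits of the same libraries tested whether chance can be excluded for each number of genes called. A chance division of the libraries can be excluded for transcripts between compartments (2712 in Control and 2532 in Restim, highest of the others 1 and 2, in each case 1 of 35 splits as large). It can also for differences of IP over input between compartments (1858 and 1430, highest of the others 0 and 0, 1 of 35 splits as large), although these fell to 0 without cell body sample 1. Every axonal input detected fewer genes (1003 to 10592) than every cell body input (10784 to 16316). Most of these calls were genes at 0 in all 4 axonal inputs. The splits therefore cannot tell a difference between compartments from a difference in genes detected. For IP over input, the libraries are paired, and 8 splits part all 4 pairs as the real one does, too few for a share under 0.05. The real split called 31 genes in Control cell bodies, 10 in Control axons, 1309 in Restim cell bodies and 3 in Restim axons, against a highest of 0, 0, 0 and 1 in the other 7 (1 of 8 as large in each). The other 24 splits that could be fitted part 2 of the 4 pairs and called at most 0, 0, 1 and 2. Between NGF states in axons chance cannot be excluded, with 6 of 35 splits as large for transcripts (1, highest other 616) and 15 of 35 for IP over input (1, highest other 11). Where the real split called 0 genes, every split gives at least as many, so the splits say nothing about chance. This holds for NGF states in cell bodies (35 of 35 splits for transcripts, highest other 2, and 35 of 35 for IP over input, highest other 0) and for the interactions (100 of 100 for transcripts, highest other 4774, and 24 of 24 for IP over input, highest other 4). The split with 616 genes parted the axonal inputs by genes detected, without overlap. On 1 side were Control inputs 1, 2 and 4 and Restim input 4 (4537 to 10592 genes). On the other were Control input 3 and Restim inputs 1, 2 and 3 (1003 to 2618 genes). The split with 4774 genes also points to a structure of the samples, whose nature was not tested.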

How the results depend on the processing

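The alternatives without RNA samples whose input held under 3000 genes, without structural RNA, on genes read in every axonal input, and without the RNA samples numbered 4 were chosen only after the data were seen; the others were fixed before. Of simulated 4-fold changes, 0% were recovered in comparisons that use axonal inputs, and whether depth, spread between libraries or loss of genes sets this was not tested. Between compartments the simulated fits called far fewer genes than the real fits, so this percentage does not measure the power of the real fits there. Leaving out the samples under 3000 genes keeps 1 Restim axonal RNA sample, so each value below that this setting gives for Restim axons rests on 1 sample. The spread in such a fit comes from the other groups, so its counts of genes say nothing about replication in Restim axons. The causes of the changes below were not tested, except that a fit on genes read in every axonal input tests fewer genes.

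The number of transcripts called between compartments was 2712 in Control and 2532 in Restim. It was 1744 and 1087 with the stricter filter, 253 and 3 with a replicate block, which assumes a pairing the labels do not state, and 239 and 72 on genes read in every axonal input. With all libraries in 1 fit it was 4345 in Control, and without the samples under 3000 genes 5772 in Restim. Leaving out 1 replicate gave 2621 to 4202 in Control and 2577 to 9064 in Restim. The 9064 came without Restim axonal library 4, so genes read in that axonal input alone were then at 0 in all axonal inputs. In the full Restim fit, 6667 genes were at 0 in 3 of the 4 axonal inputs. All 2351 genes at 0 in all 4 were called. Between NGF states in cell bodies it was 0, with DESeq2 29, and 0 to 0 with 1 replicate left out. In axons it was 1, with RLE 2, with total counts 2 and with no filter 2, and 0 with all libraries in 1 fit, without the samples under 3000 genes, and on genes read in every axonal input, with 0 to 2 when 1 replicate was left out. The interaction called 0, with DESeq2 1823, without the samples under 3000 genes 1776, and 0 to 1453 with 1 replicate left out.

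IP over input called 31 genes in Control cell bodies. It called 55 with total counts, 785 with DESeq2, 61 with no filter, 15 with the stricter filter, 0 with all libraries in 1 fit and 17 without structural RNA, and 1 to 58 with 1 replicate left out. In Restim cell bodies it called 1309, with DESeq2 2722, without the block 262, with all libraries in 1 fit 0, and 10 to 718 with 1 replicate left out. In Control axons it called 10, with DESeq2 1054, with no filter 20, without the block 1, with all libraries in 1 fit 2258, on genes read in every axonal input 6, and 0 to 21 with 1 replicate left out. In Restim axons it called 3, with DESeq2 1395, with no filter 0, with all libraries in 1 fit 1548, without the samples under 3000 genes 736, on genes read in every axonal input 0, and 0 to 4 with 1 replicate left out.

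The difference of IP over input between compartments called 1858 genes in Control, without the block 1229, on genes read in every axonal input 0, and 0 to 3190 with 1 replicate left out. In Restim it called 1430, with DESeq2 3717, without the block 1, with all libraries in 1 fit 595, without the samples under 3000 genes 3490, on genes read in every axonal input 0, and 0 to 7298 with 1 replicate left out. Between NGF states it called 0 in cell bodies, with DESeq2 19, and 0 to 0 with 1 replicate left out. In axons it called 1, with RLE 3, total counts 2, DESeq2 422, no filter 0, the stricter filter 2, no block 3, all libraries in 1 fit 0, IP libraries alone 0, without the samples under 3000 genes 10, on genes read in every axonal input 0, without structural RNA 0, and 0 to 3 with 1 replicate left out. The interaction called 0, with DESeq2 1245, the stricter filter 61, no block 1, without the samples under 3000 genes 1525, and 0 to 877 with 1 replicate left out. Of 311 list tests 57 passed, 0 with an estimated correlation.

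With IP libraries alone, which compare levels and not ratios, the log2 difference between axons and cell bodies turned to -0.25 for Syn3, -2.72 for Ngfr and -3.17 for Th in Control, and to -0.31 for Zfp462, -4.28 for Bsn, -2.90 for Efna5, -2.78 for Ngfr and -2.90 for Th in Restim. Without the samples under 3000 genes, with 1 Restim axonal sample left, IP over input of Malat1 turned to -0.83 between compartments in Restim and to -1.30 between NGF states in axons. IP over input of Trp53inp2 in Restim axons passed with all libraries in 1 fit (adjusted p = 0.0129). For Trp53inp2, the fits without the samples under 3000 genes hold 1 Restim axonal sample and cannot test replication there. RLE and total counts moved the median log2 of all genes by -0.45 and -0.15 for transcripts between Restim compartments, by -0.24 and -0.36 for the difference of IP over input between Control compartments and by -0.47 and -0.36 between Restim compartments.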

Other observations

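Mitochondrial messages took a larger mean share of counts in axons than in cell bodies in Control cultures. They made up 4.7 ± 3.1% of axonal inputs and 9.4 ± 5.4% of axonal IPs (SD, n = 4), against 1 ± 0.6% and 2 ± 0.8% in cell bodies. In Restim the shares were 1.6 ± 0.3% and 5 ± 1.1% in axons and 1.8 ± 0.4% and 3.6 ± 1.2% in cell bodies. No test of these shares was run.

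Macrophage genes summed to 196.1 ± 113.8 CPM in Control cell body inputs and 48.62 ± 63.35 CPM in Control axonal inputs, and endothelial genes to 37.93 ± 29.64 and 26.09 ± 32.01 CPM. In Restim the sums were 91.95 ± 68.89 and 19.61 ± 39.22 CPM for macrophage and 38.89 ± 6.275 and 35.38 ± 70.08 CPM for endothelial genes. Of 6 genes of circulating red cells 0 were in the table. Neat1, a nuclear RNA of paraspeckles, was 4.15-fold higher in Control axons (461.8 ± 262 and 2091 ± 1085 CPM, adjusted p = 0.0324), a call that ended without cell body library 1 or 4 or axonal library 1 (adjusted p up to 0.0972). In Restim it was at 370.3 ± 327.8 and 883.9 ± 753.6 CPM.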
